A study of Homo sapiens with 4 samples.

How the data were processed

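MicroRNA (miRNA) levels were measured in total RNA of HepG2 cells, an established human hepatocellular carcinoma line, on Agilent human miRNA arrays with a single dye, Cy3. Per the labels' protocols, RNA was extracted with TRIzol and labelled with Agilent's kit for complete labelling and hybridisation. Per the labels, cells had 48 h with benzo[a]anthracene (BA), with benzo[k]fluoranthene (BF) or with the solvent dimethyl sulfoxide (DMSO) alone, at 1% solvent in every dish. Each compound was given at its IC20, the concentration at which an effect reaches 20% inhibition, and the concentration itself is not given in the sources used here. Each compound has its own DMSO array. There were 4 groups of 1 array each. Nothing in the labels says that the 2 DMSO arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

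Per the file headers, the scanner images were read with Agilent Feature Extraction 10.7.3.1. The authors deposited its spot tables, in which intensity is the processed signal of each spot after background subtraction, with no scaling between arrays. Per the file headers, the same tables hold median spot and background intensities, an intensity total per miRNA, flags for outlying spots, and calls of whether a spot or a miRNA is above background. All 4 arrays lay on 1 slide and were read in 1 scan. Both DMSO arrays lay in column 1 and both treated arrays in column 3 of the slide, with the BA pair in row 1 and the BF pair in row 2. Slide could therefore not serve as a block, and column and treatment cannot be told apart. The deposited series table holds 1 log2 value per miRNA and array. For 296 of its 887 entries this value equals, within 0.0001, the log2 of the unscaled intensity total in the spot tables. The other 591 entries have a median of 4.32. Taken out of the log2, they rise with the summed probe totals with slopes of 0.93 to 0.96 and intercepts of 19.4 to 20.4 units (Pearson's r 0.90 to 0.97 over entries), but the step that made them is not given in the sources used here. All columns are neither centred nor scaled between arrays. The column medians of the deposited log2 values are 4.35 for the DMSO array of BA, 4.36 for BA, 4.33 for the DMSO array of BF and 4.30 for BF. That table was used only as an alternative.

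Each array has 14907 spots, of which 14192 belong to 887 human miRNAs, with 16 spots and 1 to 4 probes for each. Control spots and spots with an outlier flag were left out. The share of such outlying spots was 7.13% on the DMSO array of BA, 7.00% on BA, 7.63% on the DMSO array of BF and 6.81% on BF. No miRNA spot was saturated. The processed signals of a probe's spots were averaged, and the probes of a miRNA were averaged on the linear scale. Each array was then divided by its 75th percentile over the 492 probes well above background on all arrays (20.1% of the probes), and the log2 was taken. A probe was well above background where at least 50% of its spots were, and a miRNA was detected where any of its probes was. miRNA names are those of the array's design, which can be old, and an asterisk marks the strand of a precursor that the design lists as the minor one. The array's design header names the build hg19, and the reference table given is of GRCh38.p14, so no coordinates are printed. That table was used for names and for which miRNA genes lie next to each other, and 244 of the 258 miRNAs detected on all arrays matched it.

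A change is the log2 level on a treated array minus that on the compound's own DMSO array. With 1 array per group it carries no p-value. The error printed beside a change is the standard error over spots, which covers the spread among the spots of a probe within arrays only. It leaves out the spread between the probes of a miRNA. The spread between arrays is given by the 2 DMSO arrays, which share a slide column, so it holds no effect of column. Counts use a fixed size of 1.5-fold over miRNAs detected on both arrays of a pair. A miRNA detected on 1 array of a pair has only a bound. For it the brightest probe on the bright array is set against the higher of the lowest signal well above background and its own signal on the dim array. Where its own signal is the higher, the value is a plain ratio rather than a bound. Neither kind allows for noise.

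As a secondary test, limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to the 258 miRNAs detected on all arrays, with a Benjamini-Hochberg adjusted p of 0.05 as the threshold. The fit of DMSO, BA and BF has 1 residual degree of freedom, from the 2 DMSO arrays. It assumes that the lone treated arrays vary as these do and that slide column has no effect. Its moderated spread was effectively a single pooled SD of 0.136 on the log2 scale. A second fit took the effect common to both compounds with the pair of treated and own DMSO array as a block, again with 1 residual degree of freedom. In it the difference between the compounds serves as the error. It too cannot tell treatment from slide column.

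There were 19 lists of miRNAs, fixed before the data were examined. For each list with at least 3 measured members, the median change was placed among 10000 random lists of the same size matched on mean signal in 10 bins. These percentiles describe these arrays and are not tests. The named miRNAs were also chosen by a rule fixed before the data were examined. Per compound these were the 12 largest changes in each direction of at least 1.5-fold that kept their direction against the other DMSO array. The rule added the 5 largest bounds in each direction, the 5 largest differences between the compounds and shared changes in each direction, and the 2 to 4 brightest measured members of each list. Not every miRNA under the rule is repeated by name.

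The calculations were tested on simulated arrays with 60 changed miRNAs, made from a DMSO array's spots with noise between arrays as between the 2 DMSO arrays. No effect of slide column was simulated. The noise between arrays had the same SD for every miRNA, bright or dim, which the limma fit with its pooled SD also assumes. The false calls below therefore do not show how dim miRNAs behave on the real arrays. Of 20 miRNAs changed 1.5-fold, the size rule recovered 65% for BA and 70% for BF, and limma 90% for both. All 20 changed 2-fold and all 20 changed 3-fold were recovered by both. Among 222 unchanged miRNAs, the size rule gave 0 false calls for BA and 1 for BF, and limma gave 3 for each and 2 for the common effect. In the simulated comparison of BA with BF, where none of 282 differed, the size rule gave 9 false calls and limma 0.

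Alternatives were the 75th percentile of all probes, quantile normalization, no scaling, and normexp background correction with an offset of 50. The spot tables used here have no mean signal column, so normexp was run on the median spot and background intensities. Further alternatives were the deposited total per miRNA, the mean of the probes' log2 values, the software's detection call, the deposited series table, a filter to brighter miRNAs, other fold thresholds, the other DMSO array or the mean of both, and other limma settings. Cyclic loess between arrays, and the mean of probe log2 values with 1 floor for all arrays, were added after the data were seen. The number of arrays limits the precision of all values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.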

Results

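HepG2 cells were exposed for 48 h to 1 of 2 polycyclic aromatic hydrocarbons, benzo[a]anthracene (BA) or benzo[k]fluoranthene (BF), each at its IC20. Both compounds are products of incomplete combustion. BA consists of fused benzene rings alone, whereas BF is a larger molecule that also holds a cyclopenta-fused ring. Levels of 887 human miRNAs were compared with cells that had the solvent DMSO alone. Each of the 4 groups is 1 array, so no change below has a replicate of its own. Detected miRNAs numbered 282 on the DMSO array of BA, 291 on the BA array, 263 on the DMSO array of BF and 313 on the BF array. A total of 258 were detected on all arrays. The treated arrays were brighter than their controls. The 75th percentile of detected probes was 405 and 476 intensity units for the DMSO array of BA and for BA, and 358 and 516 units for the DMSO array of BF and for BF. Levels were scaled to this percentile.

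The 2 DMSO arrays give the background of every comparison, but without any effect of slide column. Every change sets column 3 against column 1, whereas both DMSO arrays lay in column 1. Of the 262 miRNAs detected on both, 1 was at least 1.5-fold apart, miR-181b, which was higher by 0.77 on the log2 scale on the DMSO array of BF. It is named because the count is small. The SD of the differences between the DMSO arrays was 0.19 over the miRNAs detected on all arrays. The SD of the changes over the same miRNAs was 0.46 with BA and 0.56 with BF.

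The first comparison asked which miRNAs differed after BA. miR-181b was higher by 2.43 ± 0.13 on the log2 scale (SE over spots), or 5.39-fold (1.66 against the other DMSO array), and its relative miR-181a by 1.59 ± 0.08, or 3.01-fold. Both belong to a family best known from lymphocyte development. miR-1275 (1.64 ± 0.07), miR-658 (1.57 ± 0.09), miR-198 (1.28 ± 0.08), let-7b (1.22 ± 0.11) and miR-574-5p (1.16 ± 0.06) followed. With normexp, whose offset compresses the folds of dim miRNAs, miR-181b, miR-181a, miR-658, miR-198 and let-7b were under 1.5-fold with BA, at 0.19 to 0.42. The mean signal of let-7b over all arrays was 23.7 units. miR-1275 and miR-574-5p stayed past 1.5-fold there, at 1.25 and 0.61. miR-1975, miR-431*, miR-1977_v14.0, miR-22* and miR-423-5p were higher by 0.75 to 1.02, of which miR-1977_v14.0 and miR-423-5p were at 0.56 and 0.50 against the other DMSO array. The lowest miRNAs against the control were miR-32, at -1.15 ± 0.04 or 2.22-fold lower, and miR-33a, at -1.14 ± 0.07 or 2.21-fold lower. miR-33a lies within the SREBF2 gene and acts on cholesterol transport. miR-210, the miRNA best known for its induction by hypoxia, stood at -0.996 ± 0.05, and miR-762 at -0.99 ± 0.03. miR-629*, miR-590-5p, miR-301a and miR-135a* were at -0.88 to -0.70. miR-122, the most abundant miRNA of liver tissue, was at -0.73 ± 0.06 (-0.42 against the other DMSO array), and miR-483-3p, encoded within the IGF2 gene, at -0.68 ± 0.06. On these arrays miR-122 was dim, at a mean signal of 24.8 units against 2830 for miR-192. With normexp miR-122 was at -0.32 with BA.

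In all, 23 of the 270 miRNAs detected on both arrays of the BA pair were at least 1.5-fold higher and 15 were at least 1.5-fold lower. All 38 kept their direction against the other DMSO array, where 15 of the higher and 12 of the lower ones were also past 1.5-fold. Counted against the other DMSO array alone, 16 were higher and 20 lower, so the balance of directions turned. limma called 74 of 258 miRNAs for BA against both DMSO arrays, of which 40 rose and 34 fell, and 29 of the 74 were past 1.5-fold. The split of 23 higher and 15 lower became 14 and 32 with the 75th percentile of all probes, and 50 and 6 without scaling. The limma count was 12 with the deposited total per miRNA and 0 after quantile normalization, where 79 had an unadjusted p under 0.05.

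Another 21 miRNAs were detected on the BA array but not on its control, with a bound of at least 1.5-fold for 5 of them. For miR-181d the value of 4.09-fold is a plain ratio. Its signal on the control (8.28 units) lay above the lowest one well above background there (7.77 units). The bound on the difference was at least 3.33-fold for miR-124, a miRNA of nervous tissue, and at least 1.84-fold for miR-1301. It was at least 1.60-fold for miR-28-3p and at least 1.54-fold for miR-132*. Of these 5 miR-28-3p was detected on the other DMSO array. On the control alone 12 were detected, with 2 bounds of at least 1.5-fold. miR-1208 was at least 2.53-fold lower after BA, and miR-195, which was not detected on the other DMSO array either, at least 1.59-fold lower.

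The second comparison asked the same of BF. miR-29b-1* was higher by 2.06 ± 0.06 on the log2 scale, or 4.18-fold. miR-181a was higher by 1.77 ± 0.04, miR-1290 by 1.76 ± 0.01, miR-181b by 1.68 ± 0.05, let-7b by 1.53 ± 0.11 and miR-198 by 1.52 ± 0.08. With normexp miR-181a, miR-181b, let-7b and miR-198 were under 1.5-fold with BF, at 0.037 to 0.24, whereas miR-1290 was at 1.61. Both strands of the miR-22 precursor were higher, miR-22 by 1.26 ± 0.03 and miR-22* by 1.39 ± 0.05. miR-29a, of a family that targets collagens and DNA methyltransferases, was higher by 1.25 ± 0.03. miR-658, miR-1275 and miR-574-5p were higher by 1.24 to 1.29, but with the mean of probe log2 values miR-658 was at -0.042 with BF and 0.71 with BA. Lowest was miR-33a, at -1.59 ± 0.04 or 3.02-fold lower, ahead of miR-210 at -1.37 ± 0.03 and miR-32 at -1.23 ± 0.03. miR-345 stood at -1.30 ± 0.11, miR-26b* at -1.28 ± 0.15 and miR-483-3p at -1.13 ± 0.02. miR-93* (-1.05 ± 0.44), miR-15b*, miR-148a* and miR-15a* had mean signals of 3.66 to 7.11 units, near background, with spot errors of 0.36 to 0.44. miR-345 and miR-26b* were also dim, at 9.24 and 6.46 units. miR-152 was at -0.84 ± 0.12, and miR-484 at -0.72 ± 0.02. Against the other DMSO array 5 of these were under 1.5-fold, miR-484 at -0.25, miR-15a* at -0.34, miR-15b* at -0.44, miR-93* at -0.49 and miR-152 at -0.58.

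With BF, 37 of 263 miRNAs were at least 1.5-fold higher and 22 at least 1.5-fold lower, and all 59 kept their direction against the other DMSO array. Past 1.5-fold against both DMSO arrays were 28 of the higher and 10 of the lower ones. Against the other DMSO array alone the counts were 40 and 12. limma called 98 of 258 miRNAs, of which 56 rose and 42 fell, and 52 of the 98 were past 1.5-fold. The split was 27 and 27 after quantile normalization, and 110 and 6 without scaling. After quantile normalization limma called 0, with 94 at an unadjusted p under 0.05, and with the deposited total per miRNA 25. Another 50 miRNAs were detected on the BF array but not on its control, and 0 on the control alone. This split is no count of changes, since the bound was under 1 for 35 of the 50 and at least 1.5-fold for 3. The lowest signal well above background was 5.27 units on the BF array and 9.26 on its control, and 16 of the 50 were detected on the other DMSO array. The largest bounds were at least 3.31-fold for miR-181d, at least 2.37-fold for miR-181a*, the partner strand of miR-181a, at least 1.81-fold for miR-718, and at least 1.34-fold for miR-877 and for miR-570, which was detected on the other DMSO array.

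The comparison of the compounds was made at the same labelled effect level and time. Over the 258 miRNAs detected on all arrays, 13 were at least 1.5-fold higher with both compounds, against 3.16 expected for independent lists of these sizes. At least 1.5-fold lower with both were 7, against 1.28 expected. Higher and lower with both were 8 and 9 with the 75th percentile of all probes, 37 and 3 without scaling, 3 and 2 with normexp and 13 and 4 with the control arrays exchanged. The pairs share no control array. Only 1 miRNA, miR-1915, was past 1.5-fold in opposite directions; it is named because the count is small. Across miRNAs, which are not independent replicates, the changes correlated with Pearson's r of 0.57 (bootstrap SE 0.05) and Spearman's rho of 0.44. The r was 0.65 with the control arrays exchanged.

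**Figure D1:**
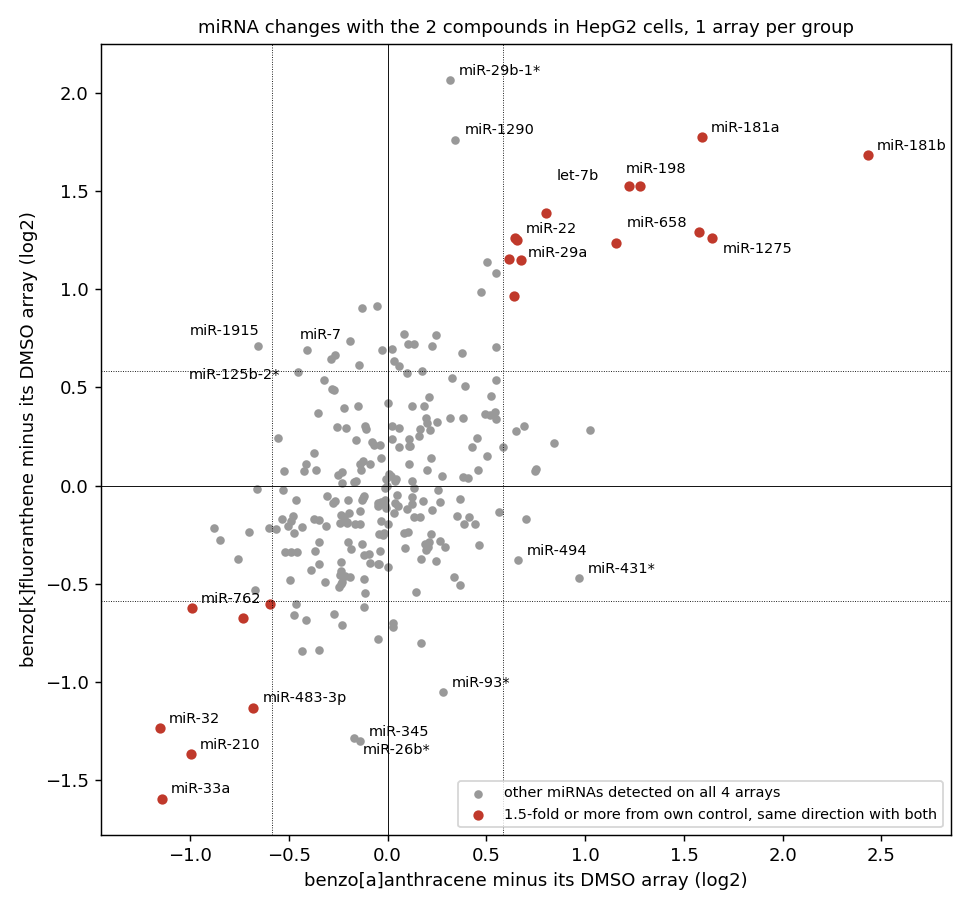
Change of each of the 258 miRNAs detected on all 4 arrays, with BA minus its DMSO array on the horizontal axis and BF minus its DMSO array on the vertical axis, both in log2 units. Dotted lines mark 1.5-fold and red points the 13 miRNAs higher and 7 lower past it with both compounds, such as miR-181a at 1.59 and 1.77 and miR-33a at -1.14 and -1.59.

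The largest shared changes upward were those of miR-181b, miR-181a, miR-1275, miR-658 and miR-198, and downward those of miR-33a, miR-32, miR-210, miR-483-3p and miR-762 (with BF at -0.52 against the other DMSO array). With normexp and its offset, several were under 1.5-fold. There miR-181b was at 0.36 with BA and 0.037 with BF, miR-181a at 0.35 and 0.23, miR-658 at 0.42 and 0.13, miR-198 at 0.38 and 0.24, and let-7b at 0.19 and 0.072. miR-33a was at -0.43 and -0.80 and miR-32 at -0.53 and -0.76, whereas miR-1275, miR-210 and miR-483-3p were past 1.5-fold with both compounds. In the limma fit with the pair as a block and Benjamini-Hochberg adjustment, 22 of 258 miRNAs were called for the effect common to both compounds, of which 17 rose and 5 fell. miR-181b rose by 2.06 ± 0.23 (limma SE, adjusted p = 0.000193), miR-181a by 1.68 ± 0.21 (adjusted p = 0.000288) and let-7b by 1.37 ± 0.21 (adjusted p = 0.000926). Each was higher on both treated arrays than on both DMSO arrays. In this fit the common effect cannot be told apart from an effect of slide column alike in both pairs. miR-33a fell by 1.37 ± 0.22 (adjusted p = 0.00104), miR-32 by 1.19 (adjusted p = 0.00206) and miR-210 by 1.18 (adjusted p = 0.00266), each lower on both treated arrays. miR-22 rose by 0.95 and miR-29a by 0.95, both with an adjusted p of 0.0195. miR-200c, which represses the ZEB transcription factors, rose by 0.88 (adjusted p = 0.0254). miR-122 (mean change -0.70, adjusted p = 0.0576) and miR-1274b (-0.60, adjusted p = 0.123) did not pass. The count was 8 when miRNAs detected on any array were tested and 0 after quantile normalization, where 46 had an unadjusted p under 0.05.

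**Figure D2:**
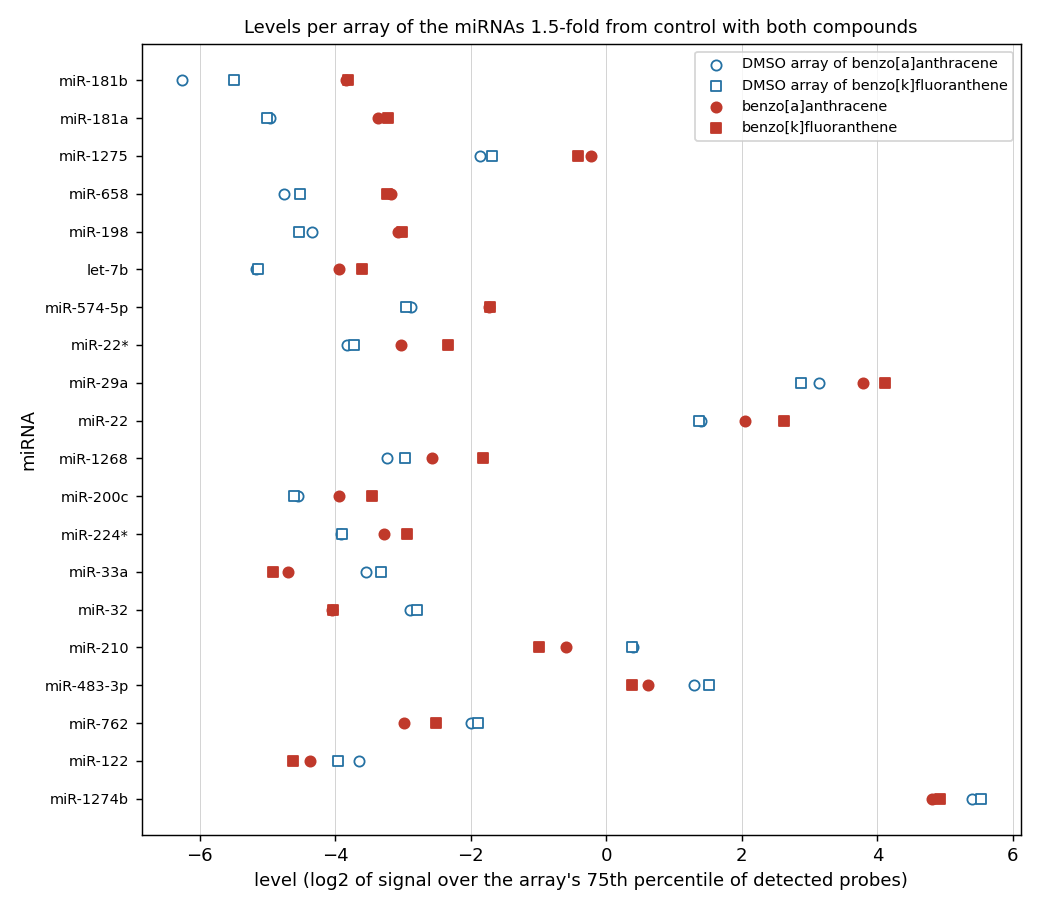
Level of the 20 miRNAs at least 1.5-fold from control in the same direction with both compounds, 1 symbol per array, as log2 of signal over the array's 75th percentile of detected probes. Open symbols are the 2 DMSO arrays and filled symbols the treated arrays; for miR-210 the DMSO arrays stood at 0.40 and 0.38 and the treated arrays at -0.60 (BA) and -0.99 (BF).

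With each compound's own DMSO array, the compounds differed most in miR-29b-1*, whose change with BA was 0.31 ± 0.07 and with BF 2.06 ± 0.06. This rank depends on the control. As BA minus BF between the treated arrays directly, miR-1290 (-1.55) and miR-1915 (-1.54) lay further apart than miR-29b-1* (-1.48). With the control arrays exchanged, miR-1915 was at -1.72 and miR-29b-1* at -1.22. Also higher with BF were miR-1290 (0.34 with BA, 1.76 with BF), miR-1915 (-0.65 and 0.71), miR-7, a repressor of EGFR (-0.41 and 0.69), and miR-125b-2* (-0.46 and 0.58). Higher with BA were miR-431* (0.97 with BA, -0.47 with BF), miR-93* (0.28 and -1.05), miR-345 (-0.14 and -1.30), miR-26b* (-0.17 and -1.28) and miR-494 (0.66 and -0.38). The other strand of the miR-431* precursor, miR-431, was not detected on any array, at a mean signal of -0.29 units. limma's direct test of BA against BF, which does not use the pairs, called 35 of 258 miRNAs, with 10 higher in BA and 25 higher in BF, and these 10 named miRNAs are among them. The 10 named miRNAs were picked as the largest differences on these same arrays. With a single pooled SD a call is close to a cutoff on size, so their calls are no independent support. The direct test also cannot tell the compounds from slide row. For miR-29b-1* the difference of BA minus BF was -1.48 (95% interval -1.86 to -1.11), and for miR-431* it was 1.24 (0.86 to 1.62). miR-494 had the largest limma adjusted p (Benjamini-Hochberg) of the 10, at 0.0376, and the DMSO arrays themselves differed by 0.50 for it. They differed by 0.56 for miR-93* and 0.34 for miR-26b*. With the control arrays exchanged the difference between the compounds was 0.20 for miR-93*, 0.43 for miR-26b* and 0.047 for miR-494, under 1.5-fold, whereas the other 7 stayed past it.

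Several shared miRNAs did not differ detectably between the treated arrays in this test. The BA minus BF difference was -0.15 for miR-181a (95% interval -0.52 to 0.23), -0.33 for let-7b (-0.71 to 0.05) and -0.02 for miR-32 (-0.40 to 0.36). For miR-181b it was -0.02 (-0.40 to 0.35), but its change against the own DMSO arrays was 0.75 larger with BA, past 1.5-fold, as the DMSO arrays differed by 0.77, so its comparison stays undecided. For 124 of the 258 miRNAs the interval lay within 1.5-fold in both directions. The interval rests on the spread of the 2 DMSO arrays. The call count of 35 became 0 both after quantile normalization, with 63 at an unadjusted p under 0.05, and with the deposited total per miRNA, with 49.

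Probes of a miRNA did not always give similar values. For miR-1290 they gave 1.25 and 1.78 with BF, for miR-1975 0.57 and 1.09 with BA, and for miR-762 -1.07 and -0.69 with BA. miR-33a, miR-198 and miR-181b had a single probe well above background on both arrays of a pair. Members of near-identical families, such as miR-181a and miR-181b, let-7b and other let-7 members, miR-29a to miR-29c, or miR-23a and miR-23b, can bind each other's probes, so the share of each member is uncertain.

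The lists of miRNAs fixed beforehand were described by the median change and its percentile among matched random lists. The all-miRNA median change was -0.01 with BA and -0.05 with BF, and without scaling it shifted to 0.22 and 0.47. With the 75th percentile of all probes it was -0.14 and -0.06, and after quantile normalization -0.02 and -0.11. Directions below are relative to the all-miRNA median, and a constant factor per array cannot turn them. The directions were therefore checked under quantile normalization and cyclic loess, and the exceptions are given. The medians printed below are not relative to the all-miRNA median. For the miR-23-27-24 clusters with BF the sign differs, as the printed -0.0020 is 0.053 relative to it.

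Liver-enriched miRNAs had a median of -0.39 with BA over 7 members (percentile 1.92) and of -0.19 with BF (percentile 9.04). Of the 7 only miR-122 was past 1.5-fold, with BA not against the other DMSO array, and the highest member with BA was at 0.00082. miR-192 was at -0.47 with BA and -0.07 with BF, miR-148a at -0.46 and -0.34, and miR-215 at -0.37 and -0.17. The list's difference between the DMSO arrays was -0.10 (percentile 15.8). The p53-responsive list had medians of 0.02 and 0.08 over 11 measured members (percentiles 73.8 and 83.9). Its most direct p53 target, miR-34a, was at 0.25 with BA and 0.32 with BF, under 1.5-fold. In this list miR-200c passed 1.5-fold with both compounds, and miR-141 (0.72, and 0.51 against the other DMSO array) with BF, named here after its value was seen. Against the other DMSO array the median of the list with BA was 0.22.

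The miR-29 family was higher with BF in all 3 members, with a median of 0.67 (percentile 97.8), though miR-29b and miR-29c were at 0.49 and 0.55 against the other DMSO array. With BA the median was 0.38 (percentile 97.3), with miR-29a at 0.66, miR-29c at 0.38 and miR-29b at -0.29. The let-7 family, repressors of RAS and LIN28 among others, had a median of -0.16 with BA (percentile 10.2) and 0.23 with BF (percentile 85.6) over 9 members. let-7b was the only member past 1.5-fold with BA, and let-7b and let-7e (0.61, and 0.31 against the other DMSO array) were with BF. The same family differed by -0.21 between the DMSO arrays (percentile 0.07), so its medians carry that offset, and with BA the median was -0.0015 against the other DMSO array. Of 13 miRNAs reported as high in liver cancer, 4 were past 1.5-fold higher and 2 lower with BF (median 0.34, percentile 98.0), and 1 higher and 3 lower with BA (median 0.13, percentile 89.2). Against the other DMSO array 2 of the 4 higher with BF and 0 of the 1 with BA were also past it, as miR-21 was at 0.48, miR-183 at 0.46 and miR-222 with BA at 0.38, and all the lower ones were. Among them miR-21, the brightest of the list, was at 0.03 with BA and 0.63 with BF, and miR-483-3p was lower with both.

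The 6 miRNAs linked to the aryl hydrocarbon receptor and its CYP1 target genes had 4 measured members, with medians of -0.07 with BA (percentile 43.9) and -0.10 with BF (percentile 33.6). Of these miR-132 was at 0.02 with BA and 0.70 with BF (0.46 against the other DMSO array), miR-27b at -0.24 and -0.19, and miR-212 at -0.13 and -0.30. The miR-17-92 cluster and its paralogs had 0 of 11 members past 1.5-fold with either compound, with medians of -0.12 and -0.07 (percentiles 49.4 and 31.4), and the BA direction flipped after quantile normalization. This list's medians against the other DMSO array were 0.02 with BA and -0.26 with BF. The miR-200 family had medians of -0.05 and 0.05 (percentiles 38.6 and 66.0), with 1 and 2 of 5 members past 1.5-fold (1 and 1 also against the other DMSO array), and its BA direction flipped after quantile normalization. The miR-30 family had 0 of 5 past 1.5-fold (medians -0.04 and 0.05, percentiles 46.6 and 51.8), with the BA direction flipped after cyclic loess. The miR-23-27-24 clusters had medians of -0.01 and -0.0020 (percentiles 70.1 and 58.5), with 1 of 5 members past 1.5-fold, miR-27a with BF at 0.69, named here after its value was seen, and the BA direction flipped after cyclic loess. Their medians against the other DMSO array were -0.09 with BA and 0.10 with BF. The miR-15-16 family had 3 measured members within 1.5-fold (medians -0.13 and 0.11, percentiles 41.9 and 57.6), with the BA direction flipped after quantile normalization. Its medians against the other DMSO array were 0.21 with BA, of the other sign, and 0.03 with BF.

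**Figure D3:**
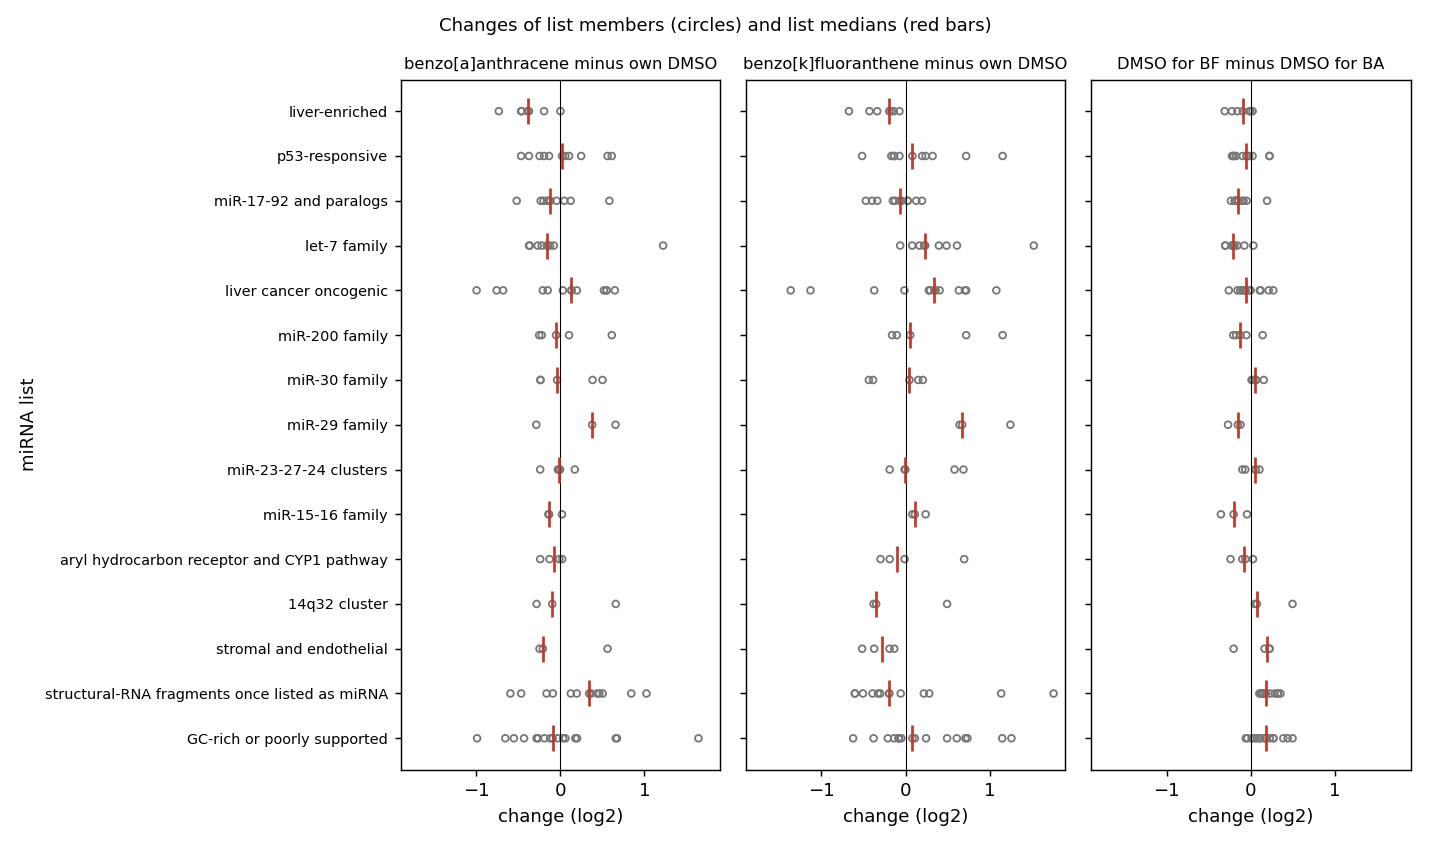
Change in log2 units of each measured member (circles) and the median (red bar) of the 15 lists with at least 3 measured members, for BA and BF against their own DMSO arrays and for the DMSO array of BF minus that of BA. The miR-29 family lies right of 0 with BF (median 0.67), and the structural-RNA list lies right of 0 between the DMSO arrays (median 0.18).

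Markers of other cell types were few. Of 8 blood-cell miRNAs and 6 muscle miRNAs, 0 were detected on both arrays of a pair. The neural list had 2 of 5 measured, miR-128 at 0.43 with BA and 0.20 with BF and miR-219-5p at -0.41 and -0.68. The stromal and endothelial list had 3 measured with BA (median -0.21, percentile 16.0) and 4 with BF (median -0.28, percentile 20.9), such as miR-145 at 0.56 and -0.13 and miR-10b at -0.21 and -0.19. Its medians against the other DMSO array were -0.0034 with BA and -0.25 with BF. The imprinted 14q32 cluster had 3 of 35 measured (medians -0.10 and -0.35, percentiles 35.8 and 6.74), with miR-494 past 1.5-fold with BA but at 0.16 against the other DMSO array, and the C19MC cluster 1 of 24, miR-512-3p, at 0.29 and -0.31. The medians of the 14q32 cluster against the other DMSO array were -0.15 with BA and 0.12 with BF, the latter of the other sign.

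Entries that stem from other structural RNAs moved with the arrays too. This list had a median of 0.34 with BA (percentile 99.0) and -0.20 with BF (percentile 3.24), the latter flipped after quantile normalization. It also differed by 0.18 between the DMSO arrays (percentile 99.99), in all 13 measured members. With BA 2 members were past 1.5-fold higher and 1 lower, and with BF 2 higher and 2 lower. Against the other DMSO array 1 of the 2 higher with BA and 0 of the 2 lower with BF were also past it, and the medians were 0.15 and 0.02. Its brightest member, miR-1974_v14.0, was at 0.37 with BA and -0.51 with BF, and miR-720 at 0.12 and -0.06. GC-rich or poorly supported entries, which often follow RNA input, had medians of -0.09 (percentile 11.6) and 0.08 (percentile 80.3) and differed by 0.18 between the DMSO arrays (percentile 99.0). Of their 17 measured members 3 were past 1.5-fold higher and 2 lower with BA, and 5 higher and 1 lower with BF. Against the other DMSO array 1 of the 3 higher with BA and 0 of the 1 lower with BF were also past it, and the others were. miR-1275, miR-1268, miR-762, miR-1915 and miR-494 belong to this list.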

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

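The tests of slide position and of GC-rich or structural-RNA entries were chosen only after the results were seen. Cyclic loess was added after the data were seen, with its test set before its result, and the test without controls was likewise set beforehand.

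Differences between the compounds were singled out because limma's test of BA against BF called 35 of 258 miRNAs. The named differences, as the change with BA minus the change with BF in log2 units, were -1.75 for miR-29b-1*, -1.42 for miR-1290, -1.37 for miR-1915, -1.10 for miR-7 and -1.04 for miR-125b-2*. In the other direction they were 1.44 for miR-431*, 1.33 for miR-93*, 1.16 for miR-345, 1.11 for miR-26b* and 1.04 for miR-494. A chance deviation of a control array could give such differences. Yet 9 of the 10 were at least 1.5-fold apart in the same direction between the treated arrays themselves, and miR-494 was the exception. The 10 were picked on differences that include the treated arrays, so this count is no independent test. With the control arrays exchanged, miR-93* was at 0.20, miR-26b* at 0.43 and miR-494 at 0.047, under 1.5-fold. The others stayed past it. Entries that follow RNA input or quality stay open, since 3 of the 10 (miR-1290, miR-1915 and miR-494) belong to the GC-rich or structural-RNA lists, against 11.6% of all measured miRNAs. A different response to the compounds stays open as well, with 1 array for each. For the treated arrays compared directly, slide row cannot be told apart from compound, as BA lay in row 1 and BF in row 2. Whether a lone treated array deviated by chance cannot be tested with 1 array per compound.

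The shared changes of the 2 compounds were weighed as the second pattern. A brightness difference that follows intensity smoothly is argued against. After cyclic loess, 95% of the 20 shared miRNAs were still past 1.5-fold in the same direction with both compounds. Background differences at single dim probes are not removed by cyclic loess and stay open. Among the brighter miRNAs alone, 4 were shared higher and 4 shared lower, and with normexp, whose offset compresses dim folds, 3 and 2. Entries that follow RNA input or quality stay open for the 4 of 20 shared miRNAs in the GC-rich or structural-RNA lists (miR-1268, miR-1274b, miR-1275 and miR-762), and whether RNA input or quality moved the others was not tested. Slide position cannot be told apart from treatment: grid control spots, unscaled, were dimmer on both treated arrays, at -0.47 for the BA pair and -0.78 for the BF pair, and both DMSO arrays lay in another column than both treated arrays. An effect of the compounds is a hypothesis that these arrays leave open.

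Of the control spots outside the main measurement, mr_1 and hur_6 were singled out because, after scaling, they were brighter on both treated arrays than on both DMSO arrays. The control probe mr_1 was higher by 0.51 with BA and 0.40 with BF on the log2 scale, and the control probe hur_6 by 0.20 and 0.067. Other control probes went the other way with BF, with hur_1 at 0.19 with BA and -0.45 with BF, hur_2 at 0.15 and -0.32, hur_4 at 0.26 and -0.14 and hur_5 at 0.030 and -0.47, and the grid spots, scaled, were at -0.70 and -1.31. What these control probes bind is not given in the sources used here.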

How the results depend on the processing

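Cyclic loess and the floor common to all arrays were chosen after seeing the data; all other alternatives were set before. Of 161 recomputed counts and correlations, 89 stayed within 1.5 times the main count, or within 1 bootstrap SE for the correlation. Of 630 recomputed named changes, 616 kept their sign and 238 moved by more than the SD between DMSO arrays. The other 14 changed sign, of which 13 were under 1.5-fold to begin with, such as miR-93* with BA (0.28, and -0.29 with the other DMSO array), miR-494 with BF (-0.38, and 0.12 there) and miR-125b-2* with BF (0.58, and -0.17 with normexp). The 1 past 1.5-fold was miR-658 with BF, at -0.042 with the mean of probe log2 values. There the floor for dim probes was lower on the BF array (0.0102 of the scale) than on its control (0.0258), and with 1 floor for all arrays (0.0258) it was at 0.63. Of the 63 named changes 53 were past 1.5-fold, against 18 with normexp, 40 without scaling, 41 in the series table and 43 with the other DMSO array. Of 210 recomputed list medians, 161 moved by less than 0.14, the SD of the list medians between DMSO arrays.

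Counts are given as BA higher, BA lower, BF higher, BF lower, shared higher and shared lower, against 23, 15, 37, 22, 13 and 7. The 75th percentile of all probes changed the BA counts to 14 and 32 and shared higher to 8. Without scaling they were 50, 6, 110, 6, 37 and 3, and in the deposited series table, also unscaled, 60, 8, 120, 5, 44 and 3. Normexp, whose offset compresses the folds of dim miRNAs, gave 5, 5, 14, 5, 3 and 2. The mean of probe log2 values gave 44 for BF lower. Of the 23 among these that were not lower before, 19 had a probe at the floor of the BF array, and with 1 floor for all arrays the count was 11. The software's detection call, with more miRNAs tested, gave 23 for BA lower. The brighter miRNAs alone gave 8, 8, 19, 7, 4 and 4. The 2-fold threshold gave 8, 2, 16, 7, 7 and 2, and a threshold of 0.36, the 95th percentile between DMSO arrays, gave 50, 42, 58, 51, 23 and 15. The other DMSO array gave 12 for BF lower and 4 for shared lower, and the mean of both DMSO arrays 4 for shared lower. The difference count between DMSO arrays, 1, became 0 with normexp, with the mean of probe log2 values under either floor, with the brighter miRNAs and at 2-fold, 2 with the deposited total, 3 with the software's call, 4 in the series table and 14 at its own 95th percentile. The correlation, 0.57, was 0.51 with the mean of probe log2 values, 0.65 with the other DMSO array and 0.67 with the mean of both. In the last case the comparisons share their controls, and simulated arrays without any change gave 0.33 (covariance 0.0090, against 0.16 observed).

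The limma counts were 74 for BA, 98 for BF, 35 for BA minus BF and 22 for both compounds. Quantile normalization gave 0 for each (79, 94, 63 and 46 at an unadjusted p under 0.05), with a prior of 0.72 degrees of freedom in the fit of the treatments and 1.27 in the paired fit. The deposited total gave 12, 25 and 0 for the first 3 (49 for the last of these at an unadjusted p under 0.05). BA gave 47 with the 75th percentile of all probes, 46 with normexp and 30 with miRNAs detected on any array. BA minus BF gave 59 with the latter. The common effect gave 49 without scaling, 10 with the mean of probe log2 values, 7 in the series table and 8 with miRNAs detected on any array, and 18 without the pair block. With the deposited total, the prior in the fit of the treatments had 2.83 degrees of freedom, against an infinite number in the main setting. Except where stated, the cause was not tested. Slide as a block was not run, as there is 1 slide. No array was left out in turn. Without a DMSO array the fit of the treatments has no residual degrees of freedom, and without a treated array the other compound's contrast and its residuals stay as they are. The fit without the pair block would keep 1 degree of freedom and was not run that way. Signal over background limits dim miRNAs: 564 of 887 were not detected on any array.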

Other observations

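The test of strands was set before its result was seen, and that of neighbouring miRNA genes took its final form only after earlier results were seen. In its first form, with far fewer names matched, neither compound lay below the 5th percentile of random relabellings. The matching was then widened, and equal weighting of clusters and separate verdicts for the compounds were added. Strands of a single precursor were measured as separate miRNAs in 52 pairs. In some of these, such as miR-16 with miR-16-2*, the first strand stems from more than a single precursor, and they were kept. With BF several pairs stood together: miR-22 at 1.26 and miR-22* at 1.39, miR-224 at 1.08 and miR-224* at 0.96, miR-21 at 0.63 and miR-21* at 0.99, miR-183 at 0.72 and miR-183* at 0.77, and miR-483-5p at -0.66 and miR-483-3p at -1.13. Others went apart, such as miR-574-5p at 1.24 and miR-574-3p at -0.07. These examples were chosen after their values were seen. Across pairs, which are not independent replicates, the changes of the strands correlated with r = 0.35 with BA and r = 0.65 with BF, above the 95th percentile of 10000 random pairings (0.23 and 0.24). Without the 2 pairs with the largest change of the first strand, r was 0.28 and 0.61. Between the DMSO arrays r was -0.13. A candidate explanation, as a hypothesis, is a change at the level of the precursor or its gene, which these arrays do not measure.

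miRNAs encoded in chains of genes, each within 10000 bases of the next, formed 135 pairs, with strands of the same precursor left out as pairs and 23 miRNAs encoded in several places left out. The pairs were made of 81 miRNAs in 23 clusters. With BF the mean absolute difference of change between cluster mates was 0.28, against 0.57 for random relabellings, and 0 of 10000 relabellings gave less. With each cluster weighted equally it was 0.39 against 0.57, and 3 of 10000 gave less. With BA it was 0.27 against 0.34, with 210 of 10000 below it, but weighting clusters equally gave 0.34 against 0.34, so BA stays undecided. Between the DMSO arrays 2312 of 10000 lay below the observed 0.21. With BF, miR-23a and miR-27a of a shared cluster were at 0.58 and 0.69, while miR-23b and miR-27b of the other were at -0.0020 and -0.19. miR-200c and miR-141 were at 1.15 and 0.72, and of the other miR-200 cluster miR-200a and miR-429 were at -0.10 and -0.16 and miR-200b, miR-200a* and miR-200b* at 0.05, 0.29 and 0.30. Other mates parted with BF, miR-132 at 0.70 from miR-212 at -0.30, and miR-134 at 0.49 from miR-494 at -0.38. These examples too were chosen after their values were seen. As a hypothesis, transcription of whole clusters may have differed after BF. Probes of similar cluster mates that bind each other's miRNA would give the same pattern, and this was not tested.

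A single entry, miR-1974_v14.0, took 48.5% of the summed miRNA signal on the DMSO array of BA, 55.4% on BA, 51.5% on the DMSO array of BF and 39.5% on BF.

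In the deposited series table, 87 of the 296 entries equal to the log2 total lie on every array below 4.32, the median of the 591 others, so a higher value in that table need not mean a brighter miRNA. The SD of the BF minus control difference is 0.11 in those 591 and 0.61 in the 296, so differences from the 2 kinds of entry are not comparable. For 64 of the 591 the software detected the miRNA on at least 1 array.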
